A study of Mus musculus with 3 samples.

How the data were processed

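RLM-RACE products from the olfactory epithelia of adult mice were hybridised to tiling arrays, 1 Stringent array and 2 High Coverage arrays, per the labels. The deposited score files give a MAT score per probe position and were made by the authors from 1 array each with no control array, with a bandwidth of 50, a maximum gap of 30 and at least 5 probes, per the file headers. MAT models the brightness of each probe from its sequence and combines standardised probes over a window. The headers give the scale as natural log, and name another probe map for Stringent than for High Coverage. The scores are relative to each array's own probes, with no scaling between arrays. The authors called regions per array at MAT score thresholds of 2.52 for Stringent, 2.53 for High Coverage 1 and 2.99 for High Coverage 2, with a false discovery rate of 0 percent, per the file headers. The region's score is the authors' own and was used only to describe and rank regions within a list. The deposited fold values of the regions were not used. The series table gives 1 promoter position with a strand per row, and the build is mm9, per the submitters' processing notes. How the authors chose the positions is not given in the sources used here. Whether they follow the probe spacing was checked, after the data were seen, by the remainder of their distance to the region's edges on division by 5 bp, at the most frequent remainder.

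A score of exactly 0 on all 3 arrays marked 5.42% of the 2313448 probes and was read as no window score, which left 2188086 scored probes. Before the data were examined, promoters had been taken to be intervals. The table holds single positions, so each was widened by 100 bp on each side. Scored probes lay in 1079 of the 1085 windows, with a median of 37 probes. The value of a promoter was its highest score as a percentile among all scored probes of that array. Shares have exact Clopper-Pearson intervals at 95%. Overlap was at least 1 bp. Random placement was drawn 100 times on scored probes. Lists were set against 10000 random lists of as many scored promoters, and for differences of percentiles between groups the lists were matched on the mean percentile in 10 bins. Random windows were matched on the number of probes in 5 bins. The clusters were separated at 1 Mb. With 1 array against 2, no test between groups with arrays as units was run and no p-value was taken across promoters. Differences between groups for a list of promoters were set against random lists, whose units are promoters. Fisher's exact test compared genes with and without a named promoter between the classes.

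Class I receptors were taken as chromosome 7 genes numbered Olfr543 to Olfr692 with Olfr33, Olfr64 to Olfr69 and Olfr78, and class II as all others. The reference gene table is of another build, GRCm38.p6, and was used for names, gene types and neighbour order only. It matched 980 of 1007 names, and 2 of 963 neighbouring pairs were in another order. The genes named in the text were set by rule: the 10 promoters with the highest lowest percentile over the arrays, the 10 highest and 10 lowest Stringent minus High Coverage differences beyond the 95th percentile of the High Coverage difference, up to 5 genes with the most promoters, and lists of well-studied receptors and of neighbours of the H and P elements. The tie among genes with 2 promoters was broken by their lowest percentile. Olfr656, Olfr33, the pseudogene named beside them and single clusters were chosen after their values were seen.

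Sequence at the promoters, distances to coding starts, cell type markers, trace amine and vomeronasal receptors and the nearest genes outside the receptor family were not analysed here, since no genome or annotation of the files' build was used. The alternatives tried were other windows, overlaps, scores, scales, class rules, cluster gaps and region lists, and each High Coverage array left out in turn. The steps were tested on simulated data. Overlaps and planted regions came out as made. For the promoter difference, 100 rises of each size were planted among 1079 promoters. With noise averaged over neighbouring probes, the percentile rule found 3 of the rises of 3 SD and 1 of the rises of 6 SD, and a median and MAD scale found 78 and 99. With independent noise, used first, the percentile rule found 1 and 3, and the other scale 99 and 99. The percentile rule was kept as planned, and both counts are given. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.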

Results

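The 5′ ends of olfactory receptor transcripts were mapped in the mouse olfactory epithelium, the tissue of the nose that holds the olfactory sensory neurons. Each neuron expresses very few genes of this large family of odorant receptors. Capped 5′ ends were amplified by RLM-RACE, in which an RNA oligonucleotide is ligated to the 5′ end of decapped mRNA. Reverse transcription used degenerate primers against receptor coding sequences, and the product was hybridised to tiling arrays. There were 3 arrays in 2 groups. Stringent, with 1 array, carried a product of nested PCR. High Coverage, with 2 arrays, carried products of PCR without nesting. Each sample pooled the epithelia of 5 adult C57/Bl6 mice aged 6 to 8 weeks. Each array read the same 2313448 probes on 20 chromosomes, with a median spacing of 5 bp. The number of arrays limits the precision, and Stringent has no replicate, and no test between the groups with arrays as units was run. Where a difference between the groups is set against random lists, the units are promoters. The exact binomial intervals below (Clopper-Pearson, 95%) cover counting error over promoters or regions only, and promoters of one array are not replicates.

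The first comparison asks how far the 2 High Coverage arrays found the same transcribed regions. The authors called 7266 regions on High Coverage 1 and 6311 on High Coverage 2. Of the High Coverage 1 regions, 57.1% (56.0 to 58.3) were overlapped by at least 1 bp by a High Coverage 2 region, against a mean of 15.6% after random placement on the tiled probes. In the other direction it was 63.8% (62.6 to 65.0) against 17.2%. Across the highest scores at 1079 named receptor promoters, the arrays correlated with Pearson's r = 0.669 and Spearman's rho = 0.629. Across all scored probes r was 0.740. These are correlations across positions, which are not independent replicates. The median absolute difference between the arrays at a promoter was 4.33 percentile points, and a few promoters differed far more. The largest gap was at an unannotated pseudogene on chromosome 19, at the 18.4 percentile on High Coverage 1 and the 97.6 percentile on High Coverage 2. Olfr656, a class I receptor on chromosome 7, reached the 97.1 percentile on High Coverage 1 and the 19.0 percentile on High Coverage 2. Olfr33 had 21.8 and 98.3. Per the file headers, the input of High Coverage 1 was named female and that of High Coverage 2 male, so a difference between these arrays cannot be separated from one between the sexes.

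The second comparison sets the nested product against the product without nesting. Stringent gave fewer and longer regions. The lists were however called at unlike cutoffs. The authors' MAT score thresholds stood for MAT p-values of 1.75e-09 on Stringent, 1.72e-06 on High Coverage 1 and 2.97e-07 on High Coverage 2. Numbers, lengths and shares of called regions are therefore not set at a like cutoff. There were 3608 regions with a median length of 265.5 bp, against 156 bp on High Coverage 1 and 167 bp on High Coverage 2. The summed length was 1208 kb on Stringent, 1362 kb on High Coverage 1 and 1334 kb on High Coverage 2. Of the Stringent regions, 50.8% (49.1 to 52.4) were overlapped by a High Coverage 1 region and 55.4% (53.7 to 57.0) by a High Coverage 2 region. Random placement gave 20.7% and 19.0%. Both High Coverage arrays overlapped 42.4% of the Stringent regions, and at least 1 of them overlapped 63.8%. When the overlap had to cover 50% of both regions, the share on both arrays was 22.3%. Across all scored probes, Stringent had r = 0.457 with High Coverage 1 and r = 0.498 with High Coverage 2. Across named promoters r was 0.0440 and 0.216, and Spearman's rho was -0.133 and 0.0672.

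The authors' table named 1085 promoter positions on mouse build mm9, on 17 chromosomes, with 521 on the plus strand. They carried 1007 receptor gene names and 51 names of unannotated pseudogenes. Of the gene names, 980 matched a receptor in the reference gene table, in each case on the same chromosome. A promoter was named for 975 of its 1110 protein-coding receptor genes, or 87.8% (85.8 to 89.7), and for 5 of its 317 receptor pseudogenes, or 1.58% (0.514 to 3.64). Genes were matched by name only, so the 51 unannotated pseudogenes and 27 unmatched gene names could not be counted. Both shares may therefore be too low, that of the pseudogenes above all. Class I receptors, an evolutionarily older class whose genes lie in 1 cluster on chromosome 7, had a named promoter for 99 of 125 genes, or 79.2%. Class II receptors, which make up the rest of the family, had one for 876 of 985 genes, or 88.9% (Fisher's exact test, two-sided p = 0.00332). The test takes genes as independent, which genes of 1 cluster may not be.

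At the named promoters the signal began at the position and ran in the direction of transcription. On Stringent, the median score was -0.945 in the bin from 100 to 50 bp upstream, 2.15 in the first 50 bp downstream and 3.27 in the next 50 bp. The highest medians of the same profile were 0.199 on High Coverage 1 and 0.613 on High Coverage 2. The mean score of the 150 bp downstream exceeded that of the 150 bp upstream at 94.5% (93.0 to 95.8) of 1041 promoters on Stringent, 70.3% on High Coverage 1 and 74.6% on High Coverage 2. The 5′ edge of the Stringent regions lay at a median of -44 bp from the named position, with quartiles of -54 and -30 bp. Called regions reached a median of 62 bp beyond their outermost probe above the authors' threshold. How the positions were chosen is not given in the sources used here. The distance from the position to the Stringent 5′ edge left the same remainder on division by 5, the median probe spacing in bp, at 312 of 669 positions, or 46.6% (42.8 to 50.5). Positions set without regard to the probes would give 20%, and the 3′ edge of the same regions gave at most 154 of 669. The positions were therefore not independent of these probes, and a rise at the position is not independent evidence.

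**Figure D1:**
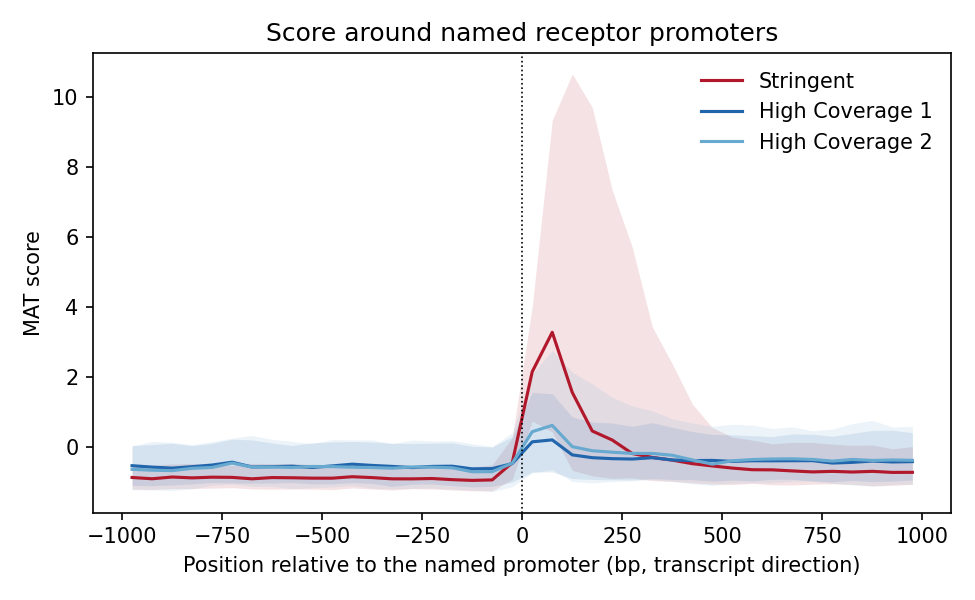
Median MAT score per 50 bp bin (vertical axis, no unit) against the position relative to the named promoter in bp, read in the direction of transcription, for each of the 3 arrays. Bands span the quartiles over promoters. The Stringent median rises from -0.945 just upstream to 3.27 between 50 and 100 bp downstream, and both High Coverage medians stay below 1.

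A called region lay within 100 bp of 669 of the 1085 positions on Stringent, or 61.7% (58.7 to 64.6). High Coverage 1 had one at 395 positions, or 36.4% (33.5 to 39.3), and High Coverage 2 at 473, or 43.6% (40.6 to 46.6). Windows of the same width 1 kb upstream, tiled for 611 promoters, had a region in 7 cases on Stringent, or 1.15%, in 55 on High Coverage 1 and in 49 on High Coverage 2, or 8.02%. All 3 arrays had a region at 188 promoters, 2 at 280, 1 at 413 and none at 204. Stringent alone had one at 307 and High Coverage alone at 212. With the window widened by 500 bp on each side, the shares were 68.5%, 58.5% and 61.8%, for which no background was measured. The gap was wider at the position itself, with 57.8%, 25.1% and 28.7%, and with the 3608 highest-scoring regions of each array, with 61.7%, 24.4% and 33.5%, both chosen after seeing the data. Positions set on Stringent signal would by themselves raise the Stringent share.

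The promoters with the highest lowest percentile over the 3 arrays were those of Olfr191, Olfr1297, Olfr1056, Olfr193, Olfr726, Olfr211, Olfr165, Olfr969, Olfr1463 and Olfr860. Olfr191 and Olfr193 are neighbours on chromosome 16, with positions 59089659 and 59111745 on the minus strand. Olfr191 scored 19.8 on Stringent, 26.0 on High Coverage 1 and 23.9 on High Coverage 2. Olfr193 scored 17.9, 30.7 and 24.6. Over all scored promoters the median percentile was 94.4 (94.0 to 94.7) on Stringent, 91.3 on High Coverage 1 and 92.4 on High Coverage 2. Random windows with matched numbers of probes had medians of 78.6, 83.6 and 81.9.

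Set promoter by promoter, 95 positions stood higher on Stringent than on High Coverage and 13 stood lower, by more than 34.3 percentile points. That limit is the 95th percentile of the difference between the 2 High Coverage arrays. By the same limit, 18 positions stood higher on High Coverage 1 than on High Coverage 2 and 36 stood lower. Among those higher were Olfr20 on chromosome 11, at the 96.8 percentile on Stringent against 6.48 and 9.33, and Olfr898 on chromosome 9, at 95.3 against 17.0 and 23.6. The others of the first 10 were Olfr1396, Olfr530, Olfr1383, Olfr1497, Olfr1348, Olfr874, Olfr1197 and an unannotated pseudogene. Olfr20 had a Stringent score of 10.7, and a High Coverage 2 region reached into its window although its highest score there was -1.61. Among those lower were Olfr424 on chromosome 1, at 22.7 against 94.3 and 99.05, and Olfr1380 on chromosome 11, at 26.7 against 92.4 and 98.7. Olfr419, Olfr115, Olfr509, Olfr444, Olfr1350, the class I receptor Olfr642 and 2 unannotated pseudogenes completed the 10 lowest. A percentile has little room above a promoter that is already high, and in simulated arrays the rule found 3 of 100 planted rises of 3 SD, against 78 of 100 on a median and MAD scale. On that scale 439 promoters were higher on Stringent and 21 lower. The simulated arrays all had the same spread of noise, so they cannot show whether that scale is common to the real arrays. Stringent had the smallest MAD of scores, 0.428 against 0.583 on High Coverage 1 and 0.656 on High Coverage 2. A like high score therefore stood higher on Stringent, and the 439 and 21 may reflect the scale of the arrays. The mean score in the window gave 254 and 22, and the window widened by 500 bp gave 49 and 27, a much smaller imbalance. These counts have no replicate check on the Stringent side. The distance from position to region edge was again divided by 5. At the 5′ edge, the same remainder was left at 46.6% on Stringent, 33.2% on High Coverage 1 and 33.6% on High Coverage 2. The 3′ edge gave at most 27.3%, on High Coverage 1, against 20% by chance. Each share covers only positions with a region on that array, and all 3 arrays read the same probes. The shares therefore tie the positions to the probes but cannot show which array's signal they follow. Positions set on Stringent signal would by themselves favour Stringent in the counts of promoters higher and lower.

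Class I promoters carried a Stringent region less often than class II promoters. Among scored positions the share was 45.2% of 104 class I positions and 63.8% of 975 class II positions. The class I share lay at the 0.02 percentile of 10000 random promoter lists of that size. On High Coverage 1 the shares were 37.5% and 36.5%, and on High Coverage 2 they were 40.4% and 44.2%, both inside the 95% range of random lists. The class I minus class II difference on Stringent, less that on the mean of the High Coverage arrays, was -17.2 points, at the 0.41 percentile of random lists. All 106 class I positions lie in 1 genomic cluster, so random lists of single promoters leave out variation between clusters. Unannotated pseudogenes, which the number rule counts with class II, also had a low Stringent share, 46.8% of 47 scored positions against 62.7% of all others (1.48 percentile of random lists). On High Coverage 1 they had 42.6% and on High Coverage 2 55.3%, and both shares were inside the 95% range of random lists. Their median percentile on High Coverage 2, 95.2, was above that range (88.0 to 94.9). Stringent minus High Coverage, their region share differed by -2.13 points, against 22.9 for all other promoters (0.44 percentile of random lists). These contrasts cover named positions only, and which positions were named may depend on signal on these arrays. Naming also differed by class, with 79.2% of class I and 88.9% of class II protein-coding genes named.

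**Figure D2:**
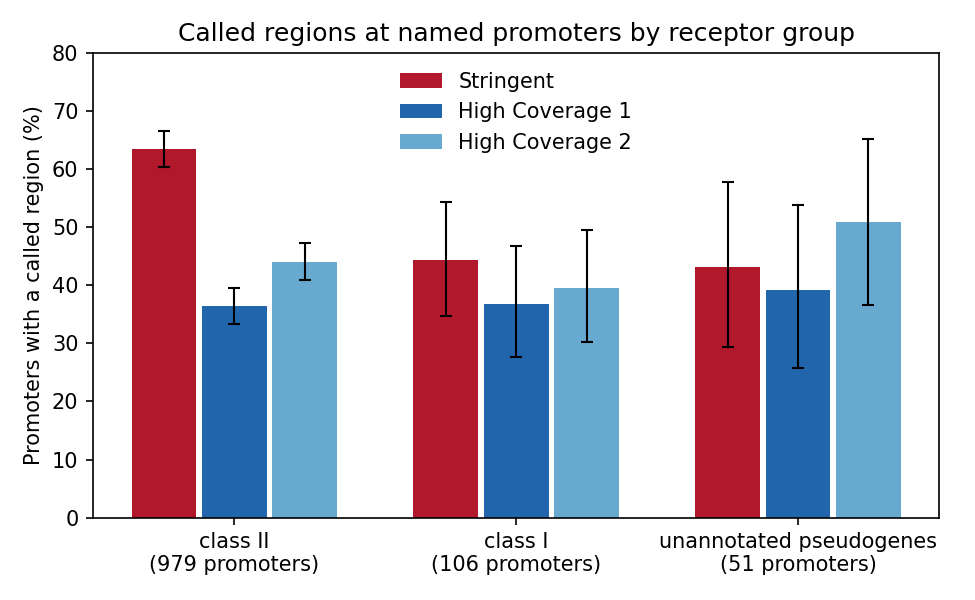
Percent of named promoters with a called region within 100 bp (vertical axis) for class II, class I and unannotated pseudogene positions on each array, with exact 95% binomial intervals as bars. All positions are counted, scored or not, and the pseudogenes are part of class II. The Stringent share of class I is 44.3% against 63.5% for class II, while the High Coverage shares of both classes lie between 36.4% and 44.0%.

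Single receptors that have been studied in detail were taken as a list of 22 genes. Of these genes, 16 had a named promoter, against 975 of all 1110 protein-coding receptor genes. Olfr16, Olfr15, Olfr151, Olfr544, Olfr124 and Olfr1019 had none. The 16 genes had 17 positions, and 14 of these had a Stringent region. High Coverage 1 had a region at 9 and High Coverage 2 at 10. The Stringent share was 82.4% against 61.7% of other promoters, at the upper bound of the 95% range of random lists. Both High Coverage shares were inside that range. The median Stringent percentile of this list, 96.8, lay just above the range of random lists (92.4 to 96.7). Olfr73, a eugenol receptor, had a region on all 3 arrays, with scores of 4.14, 4.13 and 3.79. Olfr1440, a muscone receptor, stood at the 97.6, 98.5 and 98.7 percentiles. Olfr50 scored 16.5 on Stringent but -0.770 on High Coverage 1 and 2.03 on High Coverage 2. Olfr78, a class I receptor for short-chain fatty acids, had 2 positions 13654 bp apart, and the Stringent region lay at 109894697 on chromosome 7 with a score of 12.6. Of 8 listed neighbours of the P element, a receptor enhancer on chromosome 7, 6 had a position, and Olfr715 and Olfr712 had none. All 6 with a position had a Stringent region, led by Olfr6 with a score of 18.4. On each High Coverage array 2 of the 6 had a region. Of the 7 neighbours of the H element, an enhancer on chromosome 14, 5 had a Stringent region, 3 had one on High Coverage 1 and 5 on High Coverage 2. Olfr1507, which lies nearest the H element, scored 10.5 on Stringent. Olfr713, Olfr714, Olfr17, Olfr6 and Olfr2 of the P element list and Olfr1507, Olfr1508 and Olfr1509 of the H element list are also well-studied receptors. The results of these lists are therefore not independent. With so few members, the P and H element shares lay inside the 95% range of random lists on all 3 arrays. On Stringent that range reached 100% for both lists, so no share could have lain above it. The median Stringent minus High Coverage difference of the P element neighbours, 9.87 percentile points, lay at the 99.4 percentile of matched lists. The 6 named positions of reference pseudogenes had a region at 4 on Stringent and at 2 on each High Coverage array.

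Most receptor genes had 1 named promoter. It was 1 for 980 genes, 2 for 27 and more for 0. Of the 27 genes, 15 had both positions on the same strand, at a median distance of 6098 bp (1443 to 17595). The other 12 had them on opposite strands, at a median of 4134 bp, and 11 of these pointed away from each other. As all 27 genes tied, those named here are the 5 whose lower position stood highest. They were Olfr75-ps1 on chromosome 11, Olfr676 and Olfr566 of class I and Olfr535, all 3 on chromosome 7, and Olfr1076 on chromosome 2. The positions of Olfr676 lay 1637 bp apart on opposite strands. Both had a High Coverage 2 region, with scores of 4.96 and 4.87.

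The promoters fell into 47 clusters separated by at least 1 Mb, and 22 clusters of 10 or more held 1004 promoters, or 92.5%. The largest, on chromosome 2 from 85179407 to 90238151, held 226 promoters, 63.3% of them with a Stringent region. The share was 81.8% in the cluster on chromosome 11 from 73164187 to 74175306. It was 42.5% of 113 promoters in the cluster on chromosome 7 from 109629085 to 112515652, which holds all 106 class I positions. It was 33.3% of 12 promoters on chromosome 13 from 21167971 to 21789780, where the High Coverage shares were 58.3% and 66.7%.

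Most called regions did not span a named promoter, and up to 7 kb from the nearest one they were denser downstream than upstream on all 3 arrays. A promoter was spanned by 17.4% of the Stringent regions, 3.76% of the High Coverage 1 regions and 4.99% of the High Coverage 2 regions. Between 100 bp and 10 kb from the nearest promoter, by the middle of the region, 2562 Stringent regions lay downstream and 248 upstream. The tiling itself was uneven, with 73.1% of the scored probes in this range downstream, and per scored probe the downstream rate was 3.81 times the upstream rate on Stringent, 1.56 times on High Coverage 1 and 1.66 times on High Coverage 2. Between 7 and 10 kb the direction turned on Stringent. Its 3 upstream bins of 1 kb held 22.3, 20.9 and 19.9 regions per 10000 scored probes going outwards, from 26, 20 and 16 regions, and the downstream bins 12.3, 5.60 and 4.37, from 60, 17 and 9 regions. At these distances the downstream rate stayed higher on High Coverage 1 and the order varied by bin on High Coverage 2. Of the promoters with a Stringent region, 96.7% (95.1 to 97.9) had a further region downstream before the next promoter and within 10 kb, at a median of 1487 bp. The shares were 98.2% on High Coverage 1 and 96.4% on High Coverage 2, and no background was measured. The lower quartile of the Stringent distance was 569 bp, and merging Stringent regions within 1 kb left 2282 of 3608. A further region therefore need not be a separate signal. Regions over 10 kb from a named promoter made up 13.3% of the Stringent list, 26.3% of the High Coverage 1 list and 23.6% of the High Coverage 2 list, while 37.6% of the scored probes lay there. Per 10000 scored probes this was 5.82 regions against 22.9 nearer to a promoter on Stringent, 23.3 against 39.2 on High Coverage 1 and 18.1 against 35.3 on High Coverage 2. With the 3608 highest-scoring regions of each array, chosen after seeing the data, the High Coverage shares were 24.1% and 22.3%.

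**Figure D3:**
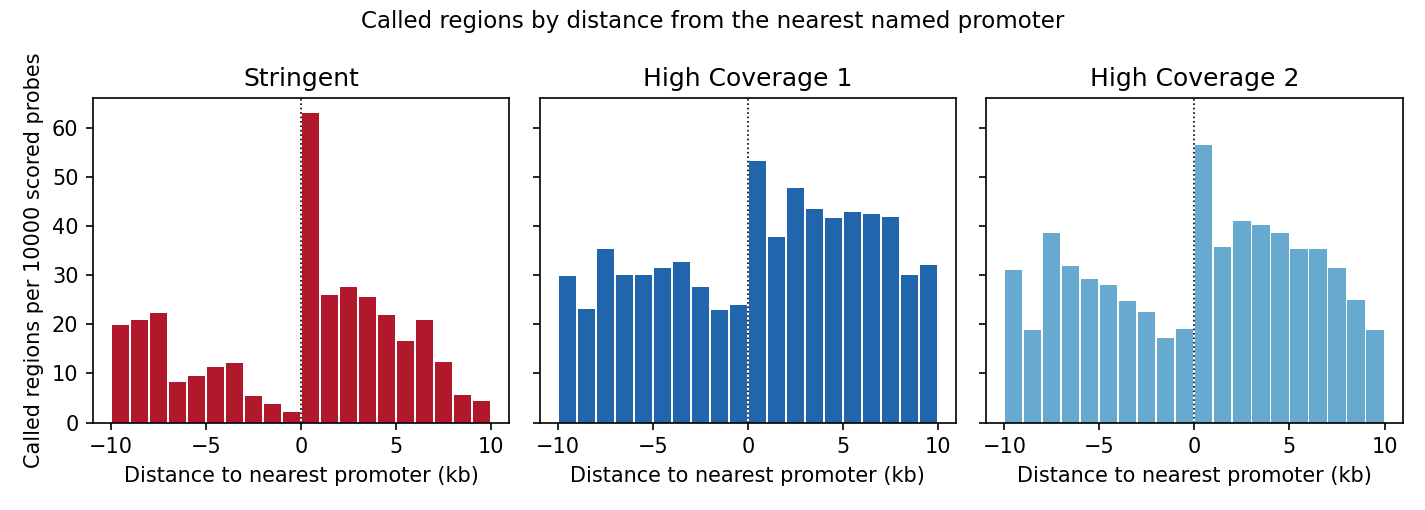
Called regions per 10000 scored probes (vertical axis) by the distance in kb from the region's middle to the nearest named promoter, in 1 kb bins, positive in the direction of transcription, with 1 panel per array. Each array has its highest bar in the first 1 kb downstream.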

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

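The tests of less RNA, of variation between clusters, of single-array noise and of a probe artefact, of promoters without a region and of the probe spacing were chosen only after the result was seen. The test on probe numbers was set before. The difference between class I and class II promoters in the share with a region, Stringent minus High Coverage, was -17.2 points, at the 0.41 percentile of random lists. The same difference between unannotated pseudogenes and all other promoters was -24.996 points, at the 0.44 percentile. Some of these pseudogenes lie in the class I cluster, so this result is not independent of that cluster.

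The first pattern is the low Stringent share of class I promoters, 45.2%, for which fewer scored probes is argued against, since class I promoters had no fewer (median 38 against 37 in class II, lower quartile 36 against 33), so that matching class II lists on probes could hardly lower their share, and it was 65.8%, with 56.7% as the lower bound of 95% of these lists. Less RNA from class I receptors stays open, by a rule that was changed after the value was seen. The class I minus class II difference on High Coverage was -1.42 points, above the -18.6 points on Stringent by more than the spread of random lists (-8.33 to 8.69), which by the first rule excludes an equal deficit. The stricter rule also allows a deficit in proportion, after taking off the upstream windows, which would be -9.46 points and is within that spread of the value. Variation between clusters cannot be told apart from class, as 2 of the 21 class II clusters with at least 10 promoters had a share as low, and class I is 1 cluster; a poorer fit of the nested primers to class I sequences was not tested.

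The second pattern is the High Coverage regions over 10 kb from a named promoter. Noise of single arrays is argued against, since 42.4% of those on High Coverage 1 and 55.6% on High Coverage 2 were overlapped by the other array, against at most 9.66% in random placements. A probe artefact shared by all arrays is consistent with the overlap by Stringent regions, up to 8.58 times that of random placement, but this covered only 13.1% of the High Coverage 1 and 17.0% of the High Coverage 2 regions. On chromosomes 5, 12 and 18, which hold no named promoter, Stringent regions overlapped 1 of 77 and 1 of 53 (1.89%, 0.0478 to 10.1). The other High Coverage array overlapped 42.9% and 62.3%. Only 4 Stringent regions were called there. If the named positions follow Stringent signal, chromosomes without one would hold little of it, so the low overlap cannot decide on an artefact. The median Stringent percentile in these High Coverage regions, 87.8 and 88.2, was above random placement (62.6 to 78.2 and 62.8 to 80.4). An artefact therefore stays open there. Transcripts without a named promoter would give the same overlap, and no biological explanation was tested.

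The third pattern is the 204 named promoters with no called region, of which 198 have scored probes. A signal under the authors' threshold may explain them, as 89.0% (81.9 to 94.0) of the 118 with a tiled upstream window scored above it on Stringent, 69.5% on High Coverage 1 and 67.8% on High Coverage 2. Positions set on these arrays would fix that outcome in advance, and those with a region were tied to the probe spacing (46.6% with the same remainder on division by 5 bp, against 20% by chance), so the explanation stays open.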

How the results depend on the processing

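No paired analysis was possible because Stringent has 1 array and the arrays share no pairing. The sequence, coding-start, marker and neighbouring-gene alternatives were not run, as no genome of the files' build was used. Of the alternatives, 54 were counted as the same and 84 as moved, and none reversed a result that had passed its test. A difference set against random lists or windows was the same if its direction and outcome held, whatever its size. The Stringent median over random windows thus counted as the same, though it went from 15.3 to 40.6 percentile points with the mean score. The cause of a move was not tested where the setting itself does not show it. The windows of 0, 50 and 200 bp, the MOR family rule and the lists of equal length were chosen only after the data were seen. Class I against class II on Stringent kept its direction and its side of the random lists under each setting run, with differences in region share from -21.9 to -18.6 points; the Stringent minus High Coverage difference ranged from -21.8 to -13.5. The signal over background of the High Coverage arrays limits what they show at single promoters.

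Merging regions within 1 kb left 2282 on Stringent, 3933 on High Coverage 1 and 3443 on High Coverage 2, and the regions above each array's median score held 1804, 3620 and 3146 by construction. With 50% of both regions required, High Coverage 1 was overlapped at 44.4%, High Coverage 2 at 51.1%, and Stringent at 29.96% by the first, 36.1% by the second and 22.3% by both. With 50% of the shorter region, these were 54.6%, 61.1%, 47.3%, 52.2% and 39.5%. With regions above the median score they were 55.1% and 62.1% between the High Coverage arrays, and 58.6% and 44.1% for Stringent on High Coverage 2 and on both. Leaving out each High Coverage array gave 50.8% to 55.4% for the last. The probe correlation of 0.740 was 0.680 by rank and 0.626 within called regions.

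Promoters with a region, in the order Stringent, High Coverage 1, High Coverage 2, any and all arrays, were 68.5%, 58.5%, 61.8%, 89.6% and 33.6% with the window widened by 500 bp, 41.0%, 24.5%, 30.6%, 61.0% and 8.66% with regions above the median score, and 57.8%, 25.1%, 28.7%, 75.9% and 8.11% at the position itself. Without Stringent, whose value stayed in its interval, they were 27.3%, 31.2%, 78.1% and 9.22% with 50% of the shorter interval, and 24.4%, 33.5%, 74.1% and 12.4% with as many regions as the smallest list. With 50 bp they were 32.2% and 38.8% on High Coverage and 13.5% on all, and with 200 bp 43.2%, 49.7% and 22.4%. Leaving out a High Coverage array gave 75.5% to 77.1% on any and 20.9% to 29.8% on all.

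The median percentile at promoters was 91.8, 67.1 and 72.7 with the mean score and 95.6, 96.0 and 95.7 with the wider window. Promoters higher on Stringent numbered 254 with the mean score, 439 on the median and MAD scale and 49 with the wider window, and those lower 22, 21 and 27; without each High Coverage array they were 104 to 123 and 12 to 13. With the wider window, class I minus class II was -0.234 percentile points on High Coverage 1 and -0.850 on High Coverage 2, the latter at the 3.07 percentile of random lists. In region share it was -1.18 points on High Coverage 1 and -7 points on High Coverage 2. With equal lists the region share differed by -3.77 and -6.37 points. All of these lay inside the 95% range of random lists, and all leaned the same way as on Stringent. Regions over 1 kb from a promoter were 67.9%, 82.8% and 80.3%, and over 10 kb 13.3%, 26.3% and 23.6%. Regions outside a promoter were 76.4%, 94.9% and 93.0% among regions above the median score, and 94.9% and 93.2% on High Coverage with equal lists.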

Other observations

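The test of a wrong strand was set before its result was seen, and that of the spacing after. Among the 12 genes with 2 named promoters on opposite strands, a wrong strand at 1 of the 2 positions is a candidate explanation. It would make 1 position of most pairs score higher on its upstream side. On Stringent, 20 of the 21 positions with probes on both sides scored higher downstream (95.2%, 76.2 to 99.9). That outcome alone would argue against a wrong strand. The positions were however tied to the probes, since the distance to the Stringent 5′ edge left the same remainder on division by 5 at 46.6% of all positions with a Stringent region and at 7 of 15 in these pairs, against 20% by chance. A position set where the signal begins on a given strand scores higher downstream whether or not the strand is right, so a wrong strand stays open. Olfr1290, on chromosome 2, was the pair that pointed towards each other, and the positions of Olfr1506 lay 96359 bp apart.

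On chromosomes 5, 12 and 18, which are tiled with 24801 probes but hold no named promoter, the authors called 4 regions on Stringent, 77 on High Coverage 1 and 53 on High Coverage 2. Per 10000 probes this was 1.61 on Stringent, against 15.6 over all chromosomes. It was 31.0 against 31.4 on High Coverage 1 and 21.4 against 27.3 on High Coverage 2, so no array had more regions there than its overall rate.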
